A study of Homo sapiens with 11 samples.

How the data were processed

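The series profiled human mesenteric arteries from diabetic and non-diabetic donors on fresh-frozen sections with 10x Visium polyA capture. The 11 sections fall by their labels into 2 diabetic arteries (6 sections) and 2 non-diabetic arteries (5 sections). The artery number in the labels was taken as 1 donor, which the labels do not state in so many words. The authors deposited raw UMI counts per gene and spot, already restricted to spots over tissue, made with Space Ranger 1.2.0 on GRCh38 per the submitters' processing notes. The annotation release and the aligner settings are not given in the sources used here. The other deposited files (spot barcodes, gene lists, spot positions and image scale factors) are neither counts nor levels; positions served for neighbouring spots and maps, and the scale factors for imaging batches. Gene names are those of the authors' files, no coordinates are given, and tissue images were not analysed here.

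Y-linked genes, XIST and TSIX (92 of 36601 genes) were left out before any step, leaving 36509. Counts of all 9872 spots over tissue were summed per artery, since sections of an artery are not independent. Genes passing filterByExpr were tested with edgeR 4.0.16 (TMM, quasi-likelihood F test, diabetic minus non-diabetic, Benjamini-Hochberg) in R 4.3.3, with an adjusted p of 0.05 as the threshold; log2 fold changes come from that fit and their standard errors from its test. CPM is counts scaled to a common library total. CPM beside a fit used TMM-scaled library sizes, while CPM of TREM2 by artery, of sections and of lists used plain totals. The 33 gene lists for cell types and pathways, fixed before the data were examined, were tested with camera of limma 3.58.1 (log CPM with a prior count of 2, preset correlation of 0.01) where at least 4 genes were in the fit, beside camera with an estimated correlation and fry. GPX1 had no row of that name. The lists overlap in TYROBP and a few other genes, and many of their genes are also made by arterial tissue. Gene p-values measure the spread between 4 arteries, and sections cut from an artery add no donors. Camera's p-values instead compare list genes with all other genes, and the preset correlation of 0.01 treats genes as nearly independent. They are therefore not a measure of the spread between arteries alone.

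Regions came from Leiden clustering in scanpy 1.11.5 of the 9275 spots with at least 100 UMIs (597 fell below). Counts were scaled to 10000 per spot, log-transformed and centred per section; 2000 variable genes, 20 principal components, 15 neighbours, a resolution of 0.5 and seed 0 were used. Regions are named by their leading genes and are not cell types; no deconvolution was run. A region was tested as above where each artery had at least 20 spots. Shares of spots were taken after thinning every spot to 247 UMIs, the 20th percentile, leaving out shallower spots. The spot overlap is a Mantel-Haenszel odds ratio over the sections of an artery, compared between groups with an exact two-sided permutation test over the 4 arteries, in which 6 labelled splits exist. Intervals of counts and shares are exact at 95% and cover counting error only. Intervals of odds ratios count each spot as independent and would be too narrow where neighbouring spots are alike. Where a group had 0 UMIs, folds were computed against 3 counts over that group's total. Such limits take UMIs as independent, so they cover counting error only and do not bound the difference between arteries. A section was called closed where its tissue, grown by 1 spot, enclosed at least 100 free grid positions; this measure was chosen after seeing the maps.

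Depth limited precision: medians per section ran from 243 to 2079 UMIs per spot. Spot diameters in image pixels split the sections into an imaging batch with non-diabetic artery 6 and diabetic artery 7 and a batch with non-diabetic artery 7 and diabetic artery 6, so each batch holds both groups. Fits were tested on simulated counts with 200 changed genes, drawn from the real means and library sizes; they gave on average 4.67 false calls over the whole section, 6.67 in the CCL19 region and 6.33 for TREM2 spots, and the CCL19 region recovered 41.2% of 4-fold and 93.9% of 8-fold changes among 9809 genes. Camera called 0.2 lists on average over 5 simulated draws without change, in which genes were independent.

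Alternatives fixed before the data were examined were DESeq2 1.42.0 (size factors and Wald test), no filter on low counts, sections as samples with the artery as a random block or ignored, the deepest section alone, thinning to 1394246 UMIs, spots with at least 250 UMIs, an equal mix of regions, artery number or imaging batch as a block, other clusterings, and leaving out each artery and section. Leaving out spots of the MT3 region or with immunoglobulin UMIs, testing lists within a region without its 10 leading genes, and the comparison of TREM2 spots with matched spots, were added after seeing the data.

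Genes were named by a rule fixed before the data were examined: up to 15 genes per direction past the threshold that separate all sections, or else the 5 with the smallest p per direction; 5 per direction in each region; up to 4 members per list past the threshold; and 13 genes of endothelial and macrophage biology whatever their values. Immunoglobulin variable segments, most HLA genes and genes with common null alleles are not named, since their level can reveal a genotype. Other genes named were chosen after their values were seen. Some results that passed or entered a list are not reported here.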

Results

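Mesenteric arteries, which carry blood to the intestine, were profiled from diabetic and non-diabetic donors by spatial transcriptomics on frozen tissue sections. In this assay (10x Visium) a section lies on a grid of barcoded spots, and each spot captures polyadenylated RNA from a small area that can hold several cells of different types. The 11 sections came from 4 arteries. Diabetic artery 6 had 4 sections and diabetic artery 7 had 2, while non-diabetic artery 6 had 3 sections and non-diabetic artery 7 had 2. Each artery number was taken as 1 donor, so group comparisons rested on 2 diabetic and 2 non-diabetic arteries. The sections held 9872 spots over tissue and 11081797 unique transcripts (UMIs). Depth per section ran from 268779 UMIs in section 2 of non-diabetic artery 6 to 1413607 UMIs in section 2 of non-diabetic artery 7. The summed arteries held 4444288 and 2467755 UMIs (diabetic 6 and 7) and 1394246 and 2775508 UMIs (non-diabetic 6 and 7), with medians of 1119, 417.5, 406 and 1738.5 UMIs per spot. The tissue closed around a lumen in 5 of the 6 diabetic sections and in 0 of the 5 non-diabetic sections, which were open strips.

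The first comparison asked which genes differ between diabetic and non-diabetic arteries over the whole section. MT3, a brain-type metallothionein that binds zinc and copper, rose in diabetic arteries by 6.96 on the log2 scale (SE 0.54), from 0.904 ± 0.151 to 123 ± 33.1 CPM (mean ± SD, n = 2 arteries each; adjusted p = 0.0269). IGLC2, an immunoglobulin lambda light chain constant gene, had 0 UMIs in both non-diabetic arteries and 481 UMIs in the diabetic ones. It was at least 96.7-fold higher, taking 3 counts over the non-diabetic group as the limit (adjusted p = 0.0468), and at least 59.2-fold without section 1 of diabetic artery 6. These limits cover counting error only and take UMIs as independent. Yet 10 spots held 88.6% and 89.1% of IGLC2 UMIs in diabetic arteries 6 and 7. IGKC, the kappa light chain constant gene, was at 145 and 56.7 CPM in diabetic arteries 6 and 7 and at 0.717 and 46.1 CPM in non-diabetic arteries 6 and 7. MT3 was higher in every diabetic section than in every non-diabetic section, whereas section 2 of diabetic artery 6 held no IGLC2. MT3 rested on 4 non-diabetic UMIs against 813 diabetic UMIs, a CPM ratio of 123 with a 95% exact counting interval from 47.7 to 451. Light chain reads can be shared between the near-identical IGLC genes, so the split between IGLC2 and IGLC3 is uncertain.

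In all, 3 genes passed the threshold among 11890 tested (3 higher, 0 lower), and 541 genes had an unadjusted p under 0.05 where 594 would by chance. DESeq2's Wald test called 20 genes, all higher in diabetic arteries. Next in line by p, but not past the threshold, were IGLC3 (0 UMIs in non-diabetic arteries, at least 27.2-fold, and at least 9.91-fold without section 4 of diabetic artery 6; adjusted p = 0.332) and the cartilage matrix gene CILP (log2 fold change 2.84, SE 0.41; adjusted p = 0.332). No gene passed in the lower direction. The smallest p values there belonged to the decoy receptor TNFRSF11B (−1.84, SE 0.38), the mitochondrial protein gene NDUFA4L2 (−1.69, SE 0.38), the matrix gene POSTN (−1.84, SE 0.42), the activin subunit INHBA (−1.71, SE 0.41) and PUM3 (−1.45, SE 0.35). Sections separated fully for 248 genes higher and 180 genes lower in diabetic tissue, against 0.433% of genes expected by chance for 6 against 5 independent sections. Sections of an artery are not independent, so these counts carry no test. All 3 calls ended with the imaging batch as a block (adjusted p = 0.0845 for MT3 and 0.158 for IGLC2) and without spots of the MT3 region described below (0.0680 for both). The sizes moved less: MT3 had a log2 fold change of 6.87 with the block and 5.74 without those spots, where IGLC2 was at least 98.9-fold higher. With 1 section left out at a time, MT3 stayed past the threshold in 9 of 11 fits, failing without section 4 of diabetic artery 6 (0.0581) and section 2 of non-diabetic artery 6 (0.0592), while IGLC2 stayed in 3 of 11.

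**Figure D1:**
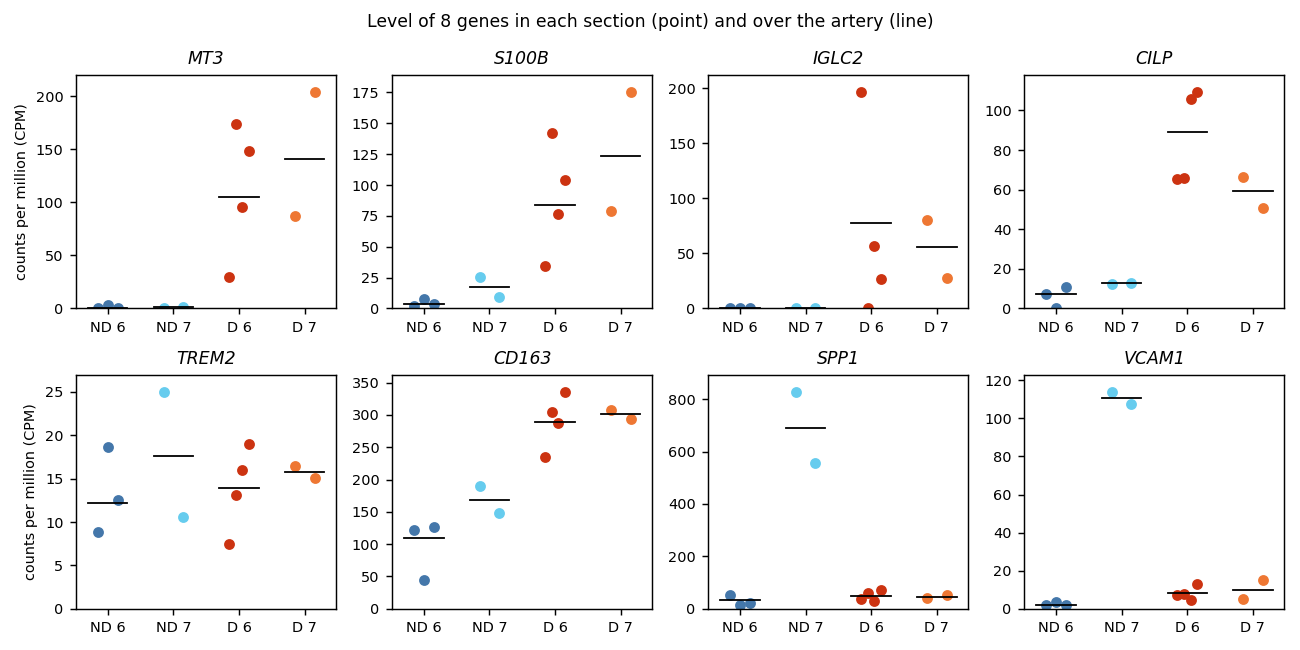
Level of MT3, S100B, IGLC2, CILP, TREM2, CD163, SPP1 and VCAM1 in CPM (vertical axes from 0), with a point for each of the 11 sections and a line at the level of the summed artery (ND non-diabetic, D diabetic). MT3 sits between 29.7 and 204 in diabetic sections and at most at 3.72 in non-diabetic ones, TREM2 overlaps between groups, and SPP1 and VCAM1 are high in both sections of non-diabetic artery 7 alone.

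Gene groups fixed in advance were then compared, and nerve sheath genes had the smallest p of the 27 lists tested. All 7 Schwann cell genes were higher in diabetic arteries, with a median log2 fold change of 2.48 (adjusted p = 1.1e-12, camera; 0.688 with an estimated correlation, as an adjusted p). Adjusted over the list alone, all 7 rose, against 1 gene over all genes tested; they included the calcium-binding S100B (3.24, SE 0.60) and the cadherin CDH19 (1.96, SE 0.47). Over the whole list the level was 411 ± 88.7 CPM in diabetic and 53.8 ± 9.07 CPM in non-diabetic arteries (n = 2 each). B and plasma cell genes were also higher (median 2.07, 5 of 5 members above 0; adjusted p = 1.0e-04, and adjusted p = 0.688 with an estimated correlation). IGHA1, the alpha heavy chain of immunoglobulin A, rose by 4.34 (SE 0.82) adjusted over the list alone, with 0 members past over all genes.

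Complement genes were higher as a group (median 0.62, 8 of 9 above 0; adjusted p = 2.5e-04, and adjusted p = 0.688 with an estimated correlation). C3, the central complement component, rose by 1.67 (SE 0.42) and CFD, the complement protease factor D, by 1.70 (SE 0.41) adjusted over the list alone, with 0 over all genes. The fibroblast list did not pass (adjusted p = 0.0872) and its members went both ways, with 7 of 12 above 0, among them DCN (1.61, SE 0.45), and COL1A1 at −0.93 (SE 0.54). Its summed level was 7826 ± 453 CPM in diabetic and 5179 ± 849 CPM in non-diabetic arteries. Elastic fibre genes, 5 of 7 above 0, did not pass either (adjusted p = 0.116), with a summed level of 3189 ± 263 and 1964 ± 14.9 CPM. Both summed levels were higher in every diabetic section than in every non-diabetic one. Endothelial genes were higher as a group (median 0.75, 9 of 12 above 0; adjusted p = 0.00260, and adjusted p = 0.759 with an estimated correlation), with levels of 310 ± 162 CPM in diabetic and 134 ± 41.7 CPM in non-diabetic arteries for VWF, the von Willebrand factor gene, and a log2 fold change of 0.75 (SE 0.37) for the junction protein PECAM1. Without non-diabetic artery 6 the adjusted p was 0.0763 for complement, 0.597 for endothelial and 0.120 for B and plasma cell genes, and without diabetic artery 7 it was 0.0663 for endothelial genes. The 7 class II antigen presentation genes all lay above 0 (median 0.62; adjusted p = 0.0282, and adjusted p = 0.759 with an estimated correlation; 0.632 without diabetic artery 7 and 0.679 without non-diabetic artery 6). No member of the endothelial and class II lists passed alone, either adjusted over the list alone or over all genes. Diabetic sections, most of which closed around a lumen, also held more tissue per section, between 734 and 1471 spots against 601 to 711 in the non-diabetic strips.

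Heat shock and matrix genes were lower as groups in diabetic arteries. Heat shock genes had a median of −0.64 with 9 of 10 below 0 (adjusted p = 3.8e-04, and adjusted p = 0.688 with an estimated correlation; 0.0763 without non-diabetic artery 6). The arteries of the groups overlapped in the summed level, with 8088 and 5074 CPM in diabetic arteries 6 and 7 and 8591 and 6086 CPM in non-diabetic arteries 6 and 7. Matrix and fibrosis genes had a median of −0.51 with 12 of 15 below 0 (adjusted p = 0.00450, and adjusted p = 0.688 with an estimated correlation), and POSTN, a matricellular protein of remodelling tissue, fell by 1.84 (SE 0.42) adjusted over the list alone, against 0 members over all genes. The matrix list stood at 15960 CPM in non-diabetic artery 7, against 9346 to 10030 CPM in the other 3 arteries, and without that artery its adjusted p was 0.247. Ribosomal protein genes had a median of −0.13 with 66 of 79 below 0 (adjusted p = 0.0209, and adjusted p = 0.797 with an estimated correlation), but only diabetic artery 6 was low. It stood at 81560 CPM, against 108200 CPM in diabetic artery 7 and 98830 and 100900 CPM in the non-diabetic arteries. Without diabetic artery 6 the direction turned (adjusted p = 0.533), and without non-diabetic artery 6 the adjusted p was 0.597.

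In all, 8 of 27 testable lists passed camera's threshold with a preset correlation of 0.01, and 0 passed with an estimated correlation or with fry. Among the other 19 lists the adjusted p ran from 0.0626 for macrophage genes (median 0.21) to 0.864 for hypoxia and glycolysis. The list of TREM2 and lipid-associated macrophage genes had a median of 0.00 and a mean of 0.09 (adjusted p = 0.147); LPL, lipoprotein lipase, rose by 2.42 (SE 0.55) adjusted over the list alone. It was also among the leading genes of the MT3 region described below (476 CPM against 17.2 CPM in other spots), and without spots of that region its log2 fold change was 1.46 (adjusted p = 0.999). Adjusted over their lists alone, the AP-1 subunit FOSB (3.18, SE 0.75) and the insulin-regulated glucose transporter SLC2A4 (2.73, SE 0.64) were also higher, while no member of these lists passed over all genes. Adjustment over a list alone, here and above, does not correct for the 27 lists searched, so single members may pass by chance. Median and test differed in sign for NF-kB inflammation (median −0.99, mean −1.37, test upward, adjusted p = 0.855), lymphatic endothelial (median −0.02, upward), hypoxia and glycolysis (0.01, downward), nuclear-encoded respiratory chain (median 0.01, mean −0.04, downward) and mitochondrially encoded genes (0.05, downward). For immediate early genes the median was −0.10 and the mean 0.14, with the test upward (adjusted p = 0.624). Too few genes were tested for 6 lists, whose diabetic and non-diabetic levels were 90.2 ± 57.6 and 27.3 ± 9.24 CPM for mast cell, 90.2 ± 64.0 and 459.9 ± 623 CPM for neutrophil, 104 ± 26.6 and 64.4 ± 12.9 CPM for mesothelial, 96.8 ± 129 and 44.9 ± 35.9 CPM for red blood cell, 12.7 ± 9.01 and 2.70 ± 0.245 CPM for pancreatic acinar, and 37.8 ± 51.5 and 0.180 ± 0.255 CPM for intestinal epithelial genes.

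Spots were next grouped by their expression into 5 regions, each named by its leading genes. The LMCD1 region was led by LMCD1, BASP1, INHBA and ITGA11. The MTRNR2L12 region was led by MTRNR2L12 and mitochondrial transcripts such as MT-ND3 and had a median of only 237 UMIs per spot. The ACTA1 region was led by ACTA1, PCP4 and ACTC1 with the smooth muscle genes ACTG2 and DES. The CCL19 region was led by the chemokine CCL19, SAA1, PLA2G2A, C3 and the complement subunit C1QC. The MT3 region, led by MT3 and S100B, held 138 and 47 spots of the diabetic arteries and 1 and 4 spots of the non-diabetic ones, too few to test within it. In diabetic arteries 6 and 7, 60.9% and 57.4% of MT3 UMIs lay in it. Region sizes are not compared between groups, because genes that define the regions differ between arteries.

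**Figure D2:**
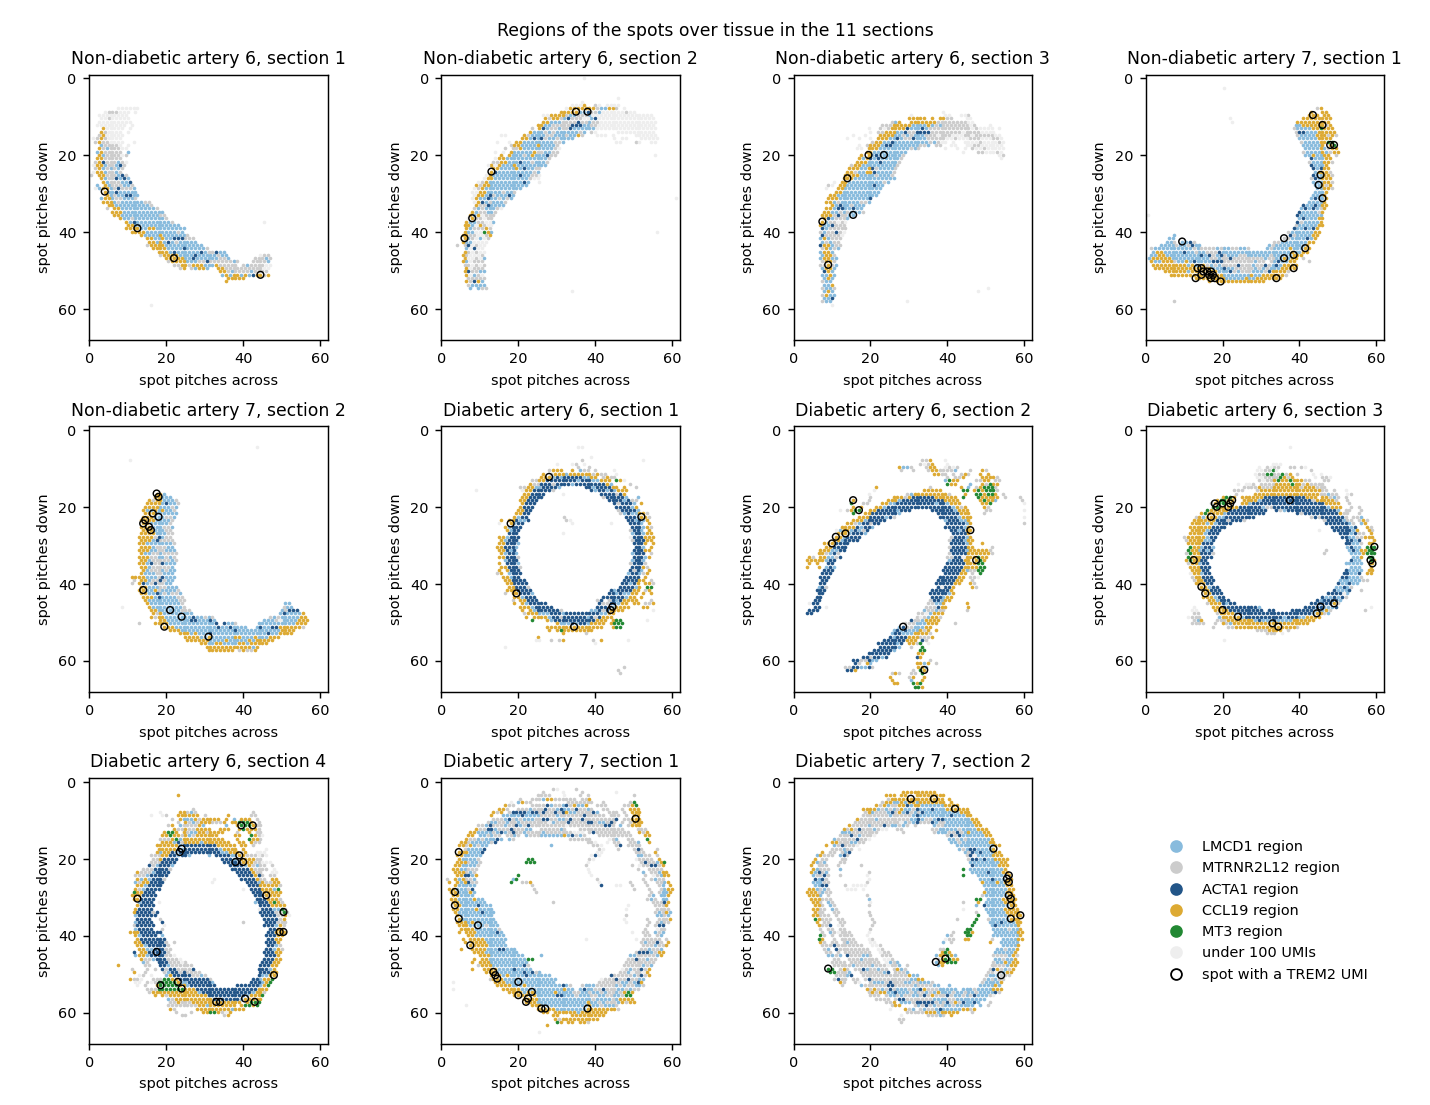
Maps of the 11 sections, with a dot for each spot over tissue coloured by region, spots under 100 UMIs in pale grey, and open circles around the spots with a TREM2 UMI; both axes count spot pitches. The diabetic sections other than section 2 of artery 6 close around a lumen, the non-diabetic sections are open strips, and 75.3% of TREM2 spots lie in the CCL19 region.

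Within regions, few genes passed the threshold between diabetic and non-diabetic arteries. In the MTRNR2L12 region, PTGDS, a prostaglandin D synthase, rose by 4.15 (SE 0.59), from 48.8 ± 33.3 to 886 ± 121 CPM (n = 2 each; adjusted p = 0.0364). In the CCL19 region, IGLC2 had 0 UMIs in non-diabetic and 419 UMIs in diabetic arteries, at least 98.6-fold higher (adjusted p = 0.0339). These were the only calls, 1 of 2432 genes and 1 of 10214 genes, with 224 and 470 genes at an unadjusted p under 0.05 (122 and 511 expected). Over the regions, 0 genes passed at a clustering resolution of 1.0, 2 genes, both lower, without centring per section, and 65 with the imaging batch as a block. The LMCD1 and ACTA1 regions gave 0 of 9165 and 0 of 1263 genes, with 426 and 59 genes at an unadjusted p under 0.05, and DESeq2's Wald test gave 11 and 1 there, 4 in the MTRNR2L12 region and 8 in the CCL19 region.

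Genes named by rank in each region did not pass the threshold. The LMCD1 region gave log2 fold changes of 2.92 for C3 (SE 0.43), 2.72 for the fibulin FBLN1 (SE 0.41), 4.43 for the apolipoprotein APOD (SE 0.72) and 2.60 for CFD (SE 0.43). The MTRNR2L12 region gave 3.97 for APOD (SE 0.65), 2.63 for FBLN1 (SE 0.47) and 2.46 for the proteoglycan DCN (SE 0.45), and IGHA1 was at least 26.3-fold higher over 0 non-diabetic UMIs. The ACTA1 region gave 4.90 for APOD (SE 1.02), 2.86 for FBLN1 (SE 0.86), 2.09 for IGFBP5 (SE 0.55) and 1.83 for the complement gene C7 (SE 0.57). The CCL19 region gave 5.74 for MT3 (SE 0.77), 3.17 for the protease inhibitor SLPI (SE 0.52) and 4.07 for IGHA1 (SE 0.69), with IGLC3 at least 27.3-fold higher. On the lower side stood ZBTB20 (−1.99), ESF1 (−1.65), SDAD1 (−1.78) and CCDC144A (−3.19) in the LMCD1 region, ESF1 (−3.26), VCAN (−2.09), ATXN2 (−2.65), CLIP1 (−2.02) and SMC4 (−3.04) in the MTRNR2L12 region, GOLGA4 (−1.92), CCN1 (−1.997), BASP1 (−1.94), SEC62 (−1.32) and EIF3A (−1.45) in the ACTA1 region, and DIO2 (−4.02), FCN1 (−4.58), TNFRSF11B (−2.31), INHBA (−2.19) and DDX21 (−2.06) in the CCL19 region. NDUFA4L2 and P2RX1, which define the LMCD1 and ACTA1 regions, are not given there as results. C3, FBLN1, CFD and C7 are leading genes of the CCL19 region, so their values in the other regions depend on which spots were placed there. The same limit holds for MT3, a leading gene of the MT3 region, in the CCL19 region. It also holds for the LMCD1 region's leading genes BASP1, in the ACTA1 region, and INHBA, in the CCL19 region.

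Complement genes were higher in diabetic arteries within the LMCD1, MTRNR2L12 and ACTA1 regions, with medians of 0.59, 1.11 and 0.42 (adjusted p = 3.7e-06, 3.4e-05 and 0.0379; adjusted p = 0.563, 0.349 and 0.825 with an estimated correlation). The CCL19 region's 10 leading genes include C3, CFD, C7, FBLN1, SFRP2 and C1QC, and so bear on which spots lay outside it. No list of the LMCD1, MTRNR2L12 or ACTA1 regions was tested without them. Within the CCL19 region, without C3, CFD and C7, the other 6 complement genes had a median of 0.54 and did not pass (camera, adjusted p = 0.0775). With these 3 the list passed (adjusted p = 2.4e-04, and adjusted p = 0.563 with an estimated correlation). Fibroblast and elastic fibre genes were also higher in the LMCD1 region (medians 0.63 and 0.53; adjusted p = 6.1e-04 and 0.00527; adjusted p = 0.563 for both with an estimated correlation), as were elastic fibre genes in the ACTA1 region (median 0.25; adjusted p = 0.0379, and adjusted p = 0.825 with an estimated correlation). Endothelial genes were higher in the LMCD1, MTRNR2L12 and CCL19 regions (medians 1.97, 2.55 and 0.49, camera adjusted p = 8.3e-08, 7.3e-07 and 0.0481). With an estimated correlation the adjusted p was 0.563, 0.349 and 0.563. The filter on low counts left 6, 4 and 12 endothelial genes in these regions, so the medians cover unlike gene sets. Macrophage genes were higher in the LMCD1 and MTRNR2L12 regions (medians 0.61 and 0.83, camera adjusted p = 3.8e-05 and 5.4e-04, and 0.699 and 0.494 with an estimated correlation). They were not past the threshold in the CCL19 region (median 0.29, adjusted p = 0.143). TREM2 and lipid-associated macrophage genes passed in the MTRNR2L12 region alone (9 genes, median 0.47, adjusted p = 0.0387, and 0.494 with an estimated correlation). Class II antigen presentation genes passed in the LMCD1 and MTRNR2L12 regions (medians 0.96 and 1.40, adjusted p = 3.8e-05 and 3.9e-04, and 0.563 and 0.494 with an estimated correlation). In the CCL19 region Schwann cell and B and plasma cell genes were higher (medians 1.61 and 1.39; adjusted p = 8.0e-05 and 8.9e-05), while heat shock, matrix and fibrosis, and interferon response genes were lower (medians −0.75, −0.72 and −1.47; adjusted p = 8.0e-05, 1.3e-04 and 0.00397). With an estimated correlation these 5 lists gave an adjusted p = 0.563, except interferon response, with 0.735. Interferon response genes stood apart in non-diabetic artery 7, at 2616 CPM in this region, while non-diabetic artery 6, at 683 CPM, lay below diabetic arteries 6 and 7 (880 and 755 CPM). The matrix list was at 16080 and 11410 CPM in non-diabetic arteries 7 and 6 and at 10050 and 8757 CPM in diabetic arteries 6 and 7. Heat shock genes were at 7446 and 5866 CPM in non-diabetic arteries 6 and 7 and at 5907 and 3702 CPM in diabetic arteries 6 and 7, so diabetic artery 6 lay level with non-diabetic artery 7.

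TREM2, a lipid-sensing receptor of macrophages named in the study's title, showed no difference beyond the spread between arteries. It reached 14.9 ± 1.31 CPM in diabetic and 14.9 ± 3.86 CPM in non-diabetic arteries (SD, n = 2 each), a difference of −0.0465 CPM (exact permutation p = 1, two-sided), and its log2 fold change was −0.04 (SE 0.41; adjusted p = 0.999). The arteries held 62 and 39 TREM2 UMIs (diabetic 6 and 7) and 17 and 49 UMIs (non-diabetic 6 and 7), with 95% Poisson intervals of 10.7 to 17.9, 11.2 to 21.6, 7.10 to 19.5 and 13.1 to 23.3 CPM. Per 1000 macrophage gene UMIs, TREM2 stood at 6.36 ± 2.04 in diabetic and 9.68 ± 5.49 in non-diabetic arteries (exact permutation p = 0.667). With every spot thinned to 247 UMIs, 0.194 ± 0.0801% of diabetic and 0.357 ± 0.0398% of non-diabetic spots held a TREM2 UMI (exact permutation p = 0.333), from only 3 to 8 spots per artery; unthinned shares were 1.60% and 1.17% in diabetic and 0.757% and 2.90% in non-diabetic arteries. With 4 arteries the smallest p this test can give is 0.333, so it could not pass a 0.05 threshold.

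TREM2 UMIs lay mostly in the CCL19 region, which held 77.8% of the 167 UMIs and 26.3% of clustered spots. There TREM2 reached 33.7 CPM, against 3.83 CPM in the LMCD1 region, and 0.588% and 0.0745% of their thinned spots held a UMI (14 of 2381 and 2 of 2686 spots; median depths 1212 and 1261 UMIs). The MT3 region stood at 57.3 CPM from few spots. Partners and markers of TREM2 macrophages gave log2 fold changes between diabetic and non-diabetic arteries of −0.06 for the adaptor TYROBP (SE 0.56), 0.61 for APOE (SE 0.44), 0.20 for GPNMB (SE 0.42), 0.00 for LGALS3 (SE 0.37), 0.30 for CD9 (SE 0.40) and 0.07 for CD68 (SE 0.68), all at an adjusted p of 0.999 or above. The scavenger receptor CD163 was at 294 ± 27.9 CPM in diabetic and 140 ± 25.8 CPM in non-diabetic arteries, higher in every diabetic section (log2 fold change 1.07, SE 0.38; adjusted p = 0.999 and unadjusted p = 0.0231, edgeR). SPP1, or osteopontin, and the adhesion genes VCAM1 and ICAM1 gave −2.88 (SE 1.07), −2.63 (SE 1.15) and −1.17 (SE 0.90), none past the threshold. Their non-diabetic level came from artery 7, at 690, 111 and 58.7 CPM, against 33.0, 2.15 and 2.87 CPM in non-diabetic artery 6. For SPP1 and TREM2 the sign turned when single arteries or sections were left out, with ranges of −3.79 to 0.34 and −0.32 to 0.34.

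The last comparison asked whether endothelial and macrophage transcripts share spots, and whether that differs in diabetes. In all 4 arteries, spots with an endothelial UMI more often held a macrophage UMI in the same spot than other spots did, with odds ratios of 3.28 (95% interval 2.70 to 3.98) and 1.27 (1.01 to 1.58) in diabetic arteries 6 and 7 and 2.62 (1.58 to 4.34) and 1.95 (1.39 to 2.73) in non-diabetic arteries 6 and 7. These intervals count each spot as independent, so they would be too narrow where neighbouring spots are alike. With macrophage UMIs looked for in neighbouring spots, diabetic artery 7 had an odds ratio of 0.999 (0.789 to 1.26), against 3.64 in diabetic artery 6 and 1.98 and 2.66 in non-diabetic arteries 6 and 7. On the log2 scale the same-spot mean was 1.03 ± 0.97 in diabetic and 1.18 ± 0.30 in non-diabetic arteries (SD, n = 2 each), a difference of −0.15 (exact permutation p = 1, two-sided; adjusted p = 1 over 13 such comparisons). This difference was −0.27 for neighbouring spots and −0.64 without thinning, where depth differs between arteries. With the region added to the section as a stratum the odds ratios were 1.18, 0.901, 1.01 and 0.991 in the same order, with intervals that all include 1. The regions came from the same spots' expression, and C1QC of the macrophage list is a leading gene of the CCL19 region. Region strata can therefore take up part of the overlap by construction. The spots with both kinds of UMI numbered 360 and 151 of 3197 and 2190 diabetic spots and 25 and 79 of 1215 and 1297 non-diabetic spots. Among the other 12 pairings of endothelial genes with a cell type list, the adjusted p ran from 0.867 to 1. The widest difference was with contractile smooth muscle genes (0.56 ± 0.30 against −2.26 ± 0.85; exact permutation p = 0.333, the smallest possible), which nearly every thinned spot held (3178 of 3197 in diabetic artery 6).

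**Figure D3:**
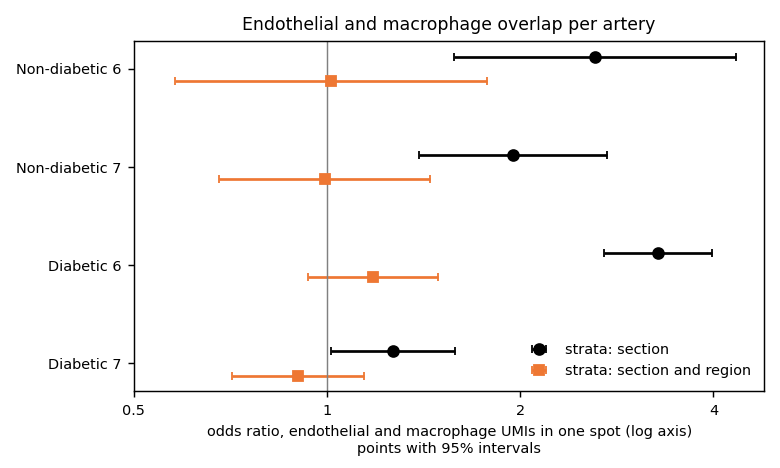
Odds ratio of finding endothelial and macrophage UMIs in the same spot for each artery, on a log axis, with points for the estimate and bars for 95% intervals, within sections (black) and within sections and regions (orange). Within sections the estimates lie between 1.27 and 3.28, and within regions between 0.901 and 1.18. Regions were drawn from the same spots' expression, and the intervals count each spot as independent.

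Sections of an artery resembled each other more than arteries of a group did. The biological coefficient of variation of edgeR was 0.144 between sections within arteries and 0.345 between arteries within groups, and the median correlation of log CPM across genes was 0.947 between sections of an artery, 0.902 between arteries of a group and 0.869 between groups. Genes are not independent replicates, so these correlations carry no test. Within arteries the coefficient was 0.156 and 0.0819 in diabetic arteries 6 and 7 and 0.149 and 0.0835 in non-diabetic arteries 6 and 7. In a check for libraries deposited more than once, pairs of sections of an artery gave a chi-square per degree of freedom between 1.70 and 7.03, above counting noise, and all were kept as separate sections. Simulated changes in data of this size and spread were recovered for 1.52% of genes at 2-fold, 31.8% at 4-fold and 84.8% at 8-fold over 11590 genes, so most changes of up to 4-fold would have been missed.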

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

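The interaction between regions, the few-spots test and the imaging batch test given here were chosen only after the results were seen. Sections of each group were screened for single values far from the rest, in 88 tests with 10 found; chance flags about 1 in 20 groups, and sections of an artery are not independent.

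Among diabetic sections, section 2 of artery 6 had the lowest total, 760487 UMIs against 1128013 to 1339742 in the others, and the highest matrix and fibrosis list level, 12210 CPM against 8811 to 9473. Section 1 of that artery had the lowest LPL, 5.78 CPM against 30.5 to 44.3, and the lowest endothelial list level, 368 CPM against 813 to 1052. Section 4 had the highest IGLC3, 81.0 CPM against at most 23.9, and the highest B and plasma cell list level, 721 CPM against 57 to 299. Section 2 of diabetic artery 7 had the highest LGALS3, 248 CPM against 179 to 202. Among non-diabetic sections, section 1 of artery 7 had the highest IGHA1, 15.4 CPM against 0 in the others, the highest C3, 355 CPM against 141 to 192, and the highest B and plasma cell list level, 158 CPM against at most 13.4.

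Light chain levels varied between sections of an artery, and a candidate explanation is that a few spots held most of the transcripts. In each diabetic artery 10 spots were enough to hold 88.6% (artery 6) and 89.1% (artery 7) of IGLC2 UMIs. IGLC2 exceeded the limit of a count of 0 in its batch partner by 25.99-fold in the weaker batch and 71.4-fold in the other. A difference between imaging batches is argued against only as far as counting error goes, since UMIs gathered in few spots are not independent. Whether diabetic arteries hold more plasma cells, or these sections met a cluster of them by chance, stays open with 2 arteries per group.

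Change with diabetes differed between the CCL19 and LMCD1 regions for 4 of 9481 genes (470 at an unadjusted p under 0.05), by an edgeR interaction term with the artery as a block. These genes were named after their values were seen. The metallothionein MT1X differed by 1.78 (SE 0.30; adjusted p = 0.00325), with diabetic and non-diabetic means of 608 and 295 CPM in the CCL19 region and 556 and 822 CPM in the LMCD1 region. MT1G, another metallothionein, differed by 4.13 (SE 0.74; adjusted p = 0.00325), with 67.2 and 6.65 CPM against 10.1 and 11.5 CPM. APOD differed by −1.78 (SE 0.32, adjusted p = 0.00325), with log2 fold changes of 2.72 in the CCL19 and 4.43 in the LMCD1 region. PHYHIP differed by 2.69 (SE 0.55, adjusted p = 0.0302), with log2 fold changes of 0.11 in the CCL19 and −2.2 in the LMCD1 region. None of the 4 passed the threshold within either region.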

How the results depend on the processing

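Leaving out spots of the MT3 region or with an immunoglobulin UMI or a region's leading genes, and all settings for TREM2 spots, were chosen only after the results were seen. Of 1272 values of named genes and lists under alternatives, 990 kept direction and side of the threshold, 65 lost the threshold, 169 gained it and 48 changed sign, 28 of them when an artery or section was left out. With 2 arteries per group, fits without an artery assume that the lone artery varies like the other group, and depth limits TREM2 to 17 to 62 UMIs per artery. Except where a setting holds fewer spots or samples, the cause was not tested. All alternatives fixed before the data were examined were run.

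Over the whole section the 3 genes became 20 with DESeq2's Wald test, 202 with no filter on low counts, 18 with sections as samples and the artery as a random block (0 of the 3 among them), 300 with sections as independent samples, whose p-values are too small, and 0 with the deepest section of each artery alone (594 at an unadjusted p under 0.05). They became 0 with the imaging batch as a block (466 at an unadjusted p under 0.05), 0 without spots of the MT3 region (480) and 1 without spots holding an immunoglobulin UMI. Leaving out an artery or section gave 0 to 410 genes: 23 and 2 without diabetic arteries 6 and 7, 410 and 333 without non-diabetic arteries 6 and 7, and 0 to 4 without single sections. The count was 2 or 3 with other size factors, thinning, spots with at least 250 UMIs or an equal mix of regions.

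Artery numbers 6 and 7 occur in both groups, and the labels do not say whether same-numbered arteries share anything more. Deviations of same-numbered arteries from their group means correlated at −0.0531. With 2 arteries per group this is by construction the mirror of the value for imaging batches (0.0531), so it cannot settle the question. With the artery number as a replicate block 0 genes passed over the whole section (422 at an unadjusted p under 0.05), 10 lists and 2 genes by region.

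The 8 lists became 0 with an estimated correlation and 0 with fry, and ranged from 7 to 14 without single arteries (14 without non-diabetic artery 7). The 2 calls by region, both higher, became 1 at a resolution of 0.3, 0 at 1.0 (edgeR; 1319 at an unadjusted p under 0.05), 2 without centring per section, both lower, 24 with DESeq2's Wald test, 65 with the imaging batch as a block, and 33 to 435 without single arteries. The 149 genes of TREM2 spots became 5 when spots were also matched on region and 35 to 189 without single arteries. The TREM2 difference of −0.0465 CPM ran from −3.70 to 3.48 CPM without single arteries or sections. The overlap difference of −0.15 became 0.0395 with region strata and ran from −0.835 to 0.54 without single arteries or sections.

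Among log2 fold changes that changed sign, TREM2 was 0.0065 with the artery as a random block, 0.68 in the deepest sections and 0.15 without spots holding an immunoglobulin UMI. TYROBP was 0.099 and 0.026 in the first 2 of these, 0.0020 with an equal mix, 0.17 with the artery number as a block and 0.16 with the imaging batch. LGALS3 was −0.0061 with DESeq2 size factors, −0.0065 with the Wald test, −0.0013 with the random block, −0.013 with independent sections, −0.20 in the deepest sections, −0.012 with at least 250 UMIs, −0.062 with an equal mix, −0.0067 and −0.0086 with the artery number and imaging batch as blocks, −0.11 without the MT3 region and −0.012 without immunoglobulin spots. CD68 was −0.032 after thinning. Without single arteries or sections the ranges were −0.32 to 0.34 for TREM2, −0.67 to 1.05 for TYROBP, −3.79 to 0.34 for SPP1, −0.14 to 0.66 for GPNMB, −0.20 to 0.16 for LGALS3, −0.68 to 1.83 for CD68, −2.003 to 2.08 for ICAM1 and −3.56 to 1.86 for VCAM1. The lower ends of SPP1, ICAM1 and VCAM1, all without non-diabetic artery 6, and the upper end of CD68, without non-diabetic artery 7, passed the threshold (adjusted p = 1.1e-05, 0.00281, 4.4e-06 and 0.0164, edgeR). Adjusted p without single arteries ran from 2.8e-07 to 0.597 for ribosomal protein, 8.7e-06 to 0.471 for macrophage and 0.00259 to 0.825 for TREM2 and lipid-associated macrophage genes, which turned direction without diabetic artery 6 (the first) or non-diabetic artery 6 (the others).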

Other observations

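The comparison of TREM2 spots, the imaging batch, depth and handling tests and their genes were chosen only after the results were seen; the test of neutrophils was written before. Spots with a TREM2 UMI (146 over the 4 arteries) were set against 5 spots each from the same section, matched on UMI totals. Median totals were close in every artery. In non-diabetic artery 7, however, 39 TREM2 spots summed to 180719 UMIs and 195 matched spots to 723973 UMIs. TREM2 spots of that artery were therefore deeper on average. Macrophage genes were higher in TREM2 spots. SPP1 rose by 1.97 (SE 0.22; adjusted p = 6.6e-06), the mucin-related FCGBP by 1.48 (SE 0.17), CD163 by 1.51 (SE 0.20), VSIG4, a complement receptor, by 1.37 (SE 0.22), the lysosomal protease CTSB by 0.90 (SE 0.15) and the TREM2 adaptor TYROBP by 1.22 (SE 0.22), each higher in 4 of 4 arteries. Contractile genes were lower, with MYH11 at −0.94 (SE 0.14), ACTA2 at −0.87 (SE 0.14) and the mural cell gene RGS5 at −1.08 (SE 0.17). In all, 149 of 2225 genes passed (63 higher, 86 lower; 398 at an unadjusted p under 0.05). As lists, macrophage genes (median 1.05; adjusted p = 1.5e-13) and class II antigen presentation genes (1.07; adjusted p = 2.0e-07) were higher and contractile genes lower (−0.80; adjusted p = 1.1e-08), with an adjusted p = 0.282, 0.319 and 0.299 with an estimated correlation.

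When the comparison spots were matched on region too, 5 genes passed, all higher: SPP1 (1.52, SE 0.21), FXYD5 (1.00, SE 0.18), CD163 (0.73, SE 0.14) and FCGBP (0.72, SE 0.14), which had passed before, and the interferon-induced ISG15 (0.89, SE 0.20). The macrophage, class II and contractile lists kept their direction there (adjusted p = 7.1e-07, 1.3e-04 and 0.00399; with an estimated correlation an adjusted p = 0.412, 0.583 and 0.730). Fibroblast, ribosomal protein, complement, and TREM2 and lipid-associated macrophage genes were higher before that matching (adjusted p = 6.1e-05, 6.3e-08, 0.00104 and 4.1e-04; with an estimated correlation an adjusted p = 0.319, 0.319, 0.447 and 0.282) and not past the threshold after it (0.392, 0.0748, 0.584 and 0.434). The effect of a TREM2 UMI differed with diabetes for 0 of 2225 genes by edgeR (83 at an unadjusted p under 0.05). Swapping the kind of spot within arteries gives 8 splits, too few for a share under 0.05: the real one gave 149 genes and the highest other gave 1.

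Non-diabetic artery 7 had the highest levels of several inflammation genes, a contrast of 1 artery with 3 that carries no test. The monocyte chemokine CCL2 reached 1377 CPM there against 12.2 to 62.8 CPM, the neutrophil and monocyte gene S100A9 609 against 12.9 to 102 CPM, S100A8 250 against 2.87 to 22.7 CPM, and IL6 61.3 against at most 5.18 CPM. CCL2 was spread widely, with a UMI in 69.3% of that artery's spots. Without this artery the log2 fold changes of SPP1, VCAM1 and ICAM1 turned to 0.34, 1.86 and 2.08. The interferon response list stood at 1730 CPM there and at 279 to 539 CPM in the other arteries. Of other blood transcripts, non-diabetic artery 7 had red blood cell genes at 19.5 CPM (5.63, 70.3 and 188 CPM in diabetic artery 6, non-diabetic artery 6 and diabetic artery 7), HBB at 0.721 CPM and 0 UMIs of the neutrophil gene FCGR3B (a count of 0 allows up to 1.081 CPM). CSF3R, another neutrophil gene, was at 25.2 CPM against 3.59 to 15.4 CPM. Diabetic artery 7 held 74.2 CPM of intestinal epithelial genes and 188 CPM of red blood cell genes, against at most 1.35 and 70.3 CPM in the other arteries.

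For this inflammation pattern the tables argue against an imaging batch and leave blood neutrophils and handling stress open. The lowest log2 ratio of SPP1, VCAM1, ICAM1, CCL2, IL6 and S100A8 over the diabetic artery of the same imaging batch was 1.88, so the batch alone does not account for these genes. They were chosen after their values were seen, and the ratio sets 1 artery against 1. In thinned spots without a neutrophil UMI the lowest log2 ratio of the 5 genes other than S100A8 over the highest other artery was 1.45, but a thinned spot of this artery was due only 0.222 neutrophil list UMIs, so that spots with 0 can still hold neutrophils and the test decides nothing. HBB and FCGR3B cannot speak against blood in the section, since both lie near the counting floor. HBB was as low in diabetic artery 6 (0.675 CPM), and FCGR3B was at most 0.45 CPM in any artery. CSF3R was highest in this artery, as was the neutrophil list. That list stood at 900 CPM here, 135.5 and 45.0 CPM in diabetic arteries 6 and 7, and 19.4 CPM in non-diabetic artery 6. The immediate early list was above the highest other artery by only 0.22 on the log2 scale, which goes against handling stress as far as that list shows it. That list alone cannot speak for every kind of handling stress. The hypoxia and glycolysis list was highest in this artery, at 2566 CPM against 1421 to 1706 CPM in the others.

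Nerve sheath transcripts were higher in diabetic arteries, as a list whose call is lost with an estimated correlation (adjusted p = 1.1e-12 preset and adjusted p = 0.688 estimated; fry 0.487). An imaging batch is argued against by a log2 ratio of the Schwann cell list of 2.53 in the weaker of the 2 batches and 3.32 in the other. Over the 5 list genes tested in both, the median log2 fold change was 2.96 after thinning and 3.24 at full depth. Random thinning of summed counts leaves expected levels unchanged, so these values cannot decide whether depth plays a part. MT3, which is not in this list, had log2 ratios of 6.60 and 7.62 within the batches. The amount of nerve tissue taken with each artery and a difference between diabetic and non-diabetic nerves both stay open, because 5 of 6 diabetic and 0 of 5 non-diabetic sections closed around a lumen and each group holds 2 arteries.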
